A study of Dorcoceras hygrometricum with 14 samples.

How the data were processed

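RNA was measured in 12 libraries from leaf explants of Boea hygrometrica taken after 0, 5, 10 or 15 days on induction medium, 3 biological replicates per day. DNA methylation was measured by bisulfite sequencing in 1 library from young leaves and 1 from mature leaves, each made from DNA mixed from 5 replicates. Groups, days and replicate numbers were taken from the labels of the samples, and the day 0 libraries were the control for expression.

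Expression values are FPKM per the file headers (fragments scaled to transcript length and to the mapped fragments of the library), computed by the authors. The submitters' processing notes name HISAT, StringTie 1.0.4, Bowtie2 2.2.5 and BSMAP without saying which tool made which file, and they state neither the genome build nor the annotation. Gene names are the locus tags and homology descriptions of the deposited table. Raw reads were not used here. The files hold no counts, so the depth of each library is unknown and no counting interval is given. FPKM totals ran from 846672 to 970083 per library. A relative depth was estimated from the most frequent ratio between libraries among FPKM values from 0.1 to 1, where a value rests on few fragments. In simulated libraries this measure often missed a known difference in depth, so it was not used to judge depth.

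The deposited methylation levels of CG regions are a fraction from 0 to 1 per the file headers. The p-value of each region is the authors' value in the deposited table, and no adjustment for multiple testing is stated. Region lists were used as deposited for the CG and CHG contexts and for the positive and negative strands in the CHH context, 4 tables in all. The region caller, its thresholds, the coverage behind each level and the weighting of sites are not stated. In the CHG and CHH tables the level columns carry sample names (BhB and BhS) that the labels do not define. These 6 columns were therefore not used, and the words Up and Down of those tables are given only as BhB relative to BhS. The table of the CHH positive strand heads its number of sites as CG, and the number is given here as sites.

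Of 24110 genes in the expression table, 17288 with at least 1 FPKM in at least 3 libraries were tested, of which 12864 had a named protein. FPKM plus a pseudocount of 1 was put on the log2 scale with no further scaling. One linear model with a mean per day was fitted over all 12 libraries in limma 3.58.1 (R 4.3.3, lmFit, then eBayes with a trend and robust variances, statmod 1.5.0). Days 5, 10 and 15 were each compared with day 0, day 10 with day 5, and day 15 with day 10. All gene tests were limma's moderated test, two-sided, with p adjusted by Benjamini-Hochberg over all genes tested. A gene was called when its adjusted p was under 0.05 and its log2 fold change was at least 1 in size. A moderated F test of the 3 comparisons with day 0 gave 1 count over the time course, with no fold minimum.

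Gene lists, 43 in all, were defined as text patterns on the homology descriptions and cover photosynthesis, the cell cycle, ribosomes, auxin and cytokinin, regeneration regulators, chromatin, stress proteins, other hormones, cell walls and pigments, sugars, markers of cell types, and reference genes. Some members do not do what a list's name says, and the text names only a part of those called. Lists were tested with limma's camera with its preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 43 lists of a comparison, and again with the correlation estimated from the data. camera compares a list with all other genes, whose median lay above 0 against day 0, so its direction can differ from the sign of a list's median. Members called are counted with the adjustment over all genes and adjusted over the list alone.

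Named genes followed a rule. Against day 0 they were the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change whose 3 libraries did not overlap between the days, with a mean of at least 10 FPKM in the higher group, a named protein and 1 gene per protein name. The successive comparisons took 5 and 5, and each list took up to 2 called higher and 2 called lower members with the smallest adjusted p and a mean of at least 1 FPKM. For CG regions the rule took the 3 regions with the largest positive and the 3 with the largest negative difference that the table ties to a named protein, and up to 10 regions of list genes. The text names a part of these, chosen after their values were seen and mostly among the calls that held when each library was left out. The comparisons, tests, thresholds, lists, the rule and most alternatives were set before the data were examined.

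The 3 comparisons with day 0 share their control libraries. To show what sharing alone gives, 20 data sets were simulated with no change between days and with each gene's own variance, and the correlation and the covariance of the fold changes were recorded. The simulated libraries were independent of each other. Replicate numbers were checked for pairing by correlating, across genes, the deviations of libraries from their day's mean. Against day 0, libraries with the same number gave correlations from -0.011 to 0.21, and the model holds no replicate term. At days 10 and 15 each of these lay above the highest value with another number. At day 5 this held for replicate 3 (0.20 against -0.13) but not for replicates 1 (0.16 against 0.19) and 2 (-0.011 against 0.06). For day 10 against day 5 libraries with the same number gave 0.28, 0.18 and 0.66 for replicates 1, 2 and 3, and for day 15 against day 10 they gave 0.44, 0.23 and 0.50. The labels name no shared plant or batch, so results with replicate number as a block are given as an alternative.

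In simulated data with 200 changed genes among 17288, the fit recovered 78% of 50 at a log2 change of 1.5. It recovered 94% at 2 and 98% at 3 and 4, with 0 in the wrong direction and 11 other genes called. Recovery on real data is unknown.

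Regions were counted by context and direction, and lists were intersected with bedtools 2.31.1 with at least 1 bp shared. Genes were tied to regions only by the locus tags in the region tables, which place a region in an exon, in coding sequence, or within 2 kb upstream or downstream. The share of genes called in any comparison with day 0, in each direction and at each day was compared between genes with a region and all other genes tested with Fisher's exact test, two-sided (scipy 1.17.1), in 30 tests adjusted by Benjamini-Hochberg. Called genes whose regions all went 1 way were compared with these by direction in 4 further exact tests. With 1 library per leaf age, no test between leaf ages was made.

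Alternatives were a pseudocount of 0.1, no filter, no fold minimum, limma without trend and robust variances, a fit on only the 6 libraries compared, replicate number as a block, median-ratio rescaling, and each library left out in turn. Where a library is left out, its day has a pair of libraries and the spread is pooled over all days. For regions they were p under 0.005, a level difference at or above the median, overlap of at least 0.5 of the shorter region, and a logistic model with mean expression (statsmodels 0.14.6). A fit on replicates 1 and 2 only, a background of genes on the same scaffolds, and the sign of the fold change at day 15 were added after the data were seen, as were list tests on replicates 1 and 2 with an estimated correlation. Tables were read with pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.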

Results

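Gene expression was measured by RNA sequencing in leaf explants of Boea hygrometrica, a desiccation-tolerant plant of the Gesneriaceae that regenerates shoots from leaf pieces. The explants came from the young leaves of 1-month-old plants and were segments with sides of 0.5 cm. They were kept for 0, 5, 10 or 15 days on a medium with 0.1 mg/L of the auxin 2,4-D and 0.1 mg/L of the cytokinin 6-BA. Each of the 4 days had 3 biological replicate libraries, and each replicate came from 30 leaf discs. DNA methylation was measured in young leaves of 1-month-old plants and mature leaves of 6-month-old plants, 1 bisulfite library each, with 44.49 Gb and 41.19 Gb of clean bases per the labels. The expression table listed 24110 genes in FPKM, of which 17288 were tested. Read counts per library were not used here, so the depth behind each value is unknown. Between 15531 and 16496 genes per library reached 1 FPKM, and the 20 highest genes made up 10.4% to 19.3% of a library's total. Within each day replicate 3 had the fewest genes at 0 FPKM (5226, 5367, 5028 and 5180 at days 0, 5, 10 and 15).

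Day 0 libraries stood apart from the later days along the first principal component (31.9% of the variance). Replicate 3 of each day stood apart from replicates 1 and 2 along the second (23.3%). Across genes, which are not independent replicates, replicates 1 and 2 of a day correlated with r = 0.965, 0.971, 0.943 and 0.956 at days 0, 5, 10 and 15. The lowest correlation within a day was 0.919, 0.922, 0.896 and 0.913, each time with replicate 3. With the day kept in the model, 860 genes differed between the replicate 3 libraries and the others (621 higher and 239 lower). By the same comparison limma called 0 genes for replicate 1 and 0 for replicate 2. Mitosis and cytokinesis genes were higher in replicate 3 by a median log2 difference of 0.40 (camera adjusted p = 0.00889), and Calvin cycle genes were lower by a median of -0.64 (adjusted p = 6.07e-05). Of the 43 lists, 10 differed in replicate 3 with the preset correlation, and their adjusted p with an estimated correlation ran from 0.423 to 0.681. The other 8 are given beside the gene groups they concern.

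**Figure D1:**
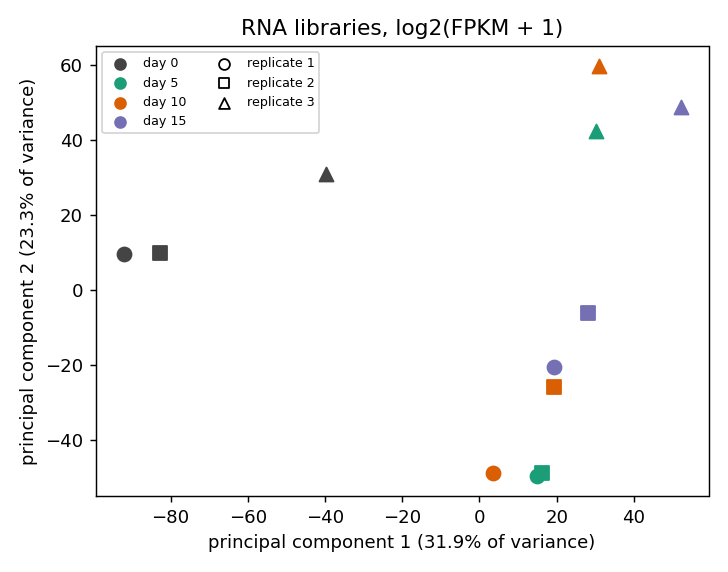
Principal components of log2(FPKM + 1) of the 17288 tested genes, 1 point per library, with colour for the day and marker shape for the replicate number. The first component holds 31.9% of the variance and parts day 0 (at most -39.8) from the later days (at least 3.38), and the second holds 23.3% and has replicate 3 highest at each day.

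The first comparison asked which genes differed after 5 days on induction medium. CURVATURE THYLAKOID 1B (F511_10460), which bends thylakoid membranes at the margins of grana, fell from 520 ± 86.9 FPKM at day 0 to 5.61 ± 2.28 at day 5 (mean ± SD, n = 3 here and for all FPKM values), a log2 fold change of -6.35 (SE 0.56, adjusted p = 0.000817). LOB domain-containing protein 25-like (F511_25101), of a family of transcription factors that act in lateral organ and root initiation, rose from 4.51 ± 1.09 to 54.3 ± 9.56 (3.33, SE 0.27, adjusted p = 0.000794). A lignin-forming anionic peroxidase-like gene (F511_06406) rose from 12.4 ± 1.27 to 429 ± 257 (4.82, SE 0.49, adjusted p = 0.00114), and an extracellular ribonuclease LE-like gene (F511_39535) from 3.07 ± 1.35 to 107 ± 28.4 (4.76, SE 0.28, adjusted p = 5.95e-05). The stress-related transcription factor WRKY53 (F511_00576) fell from 229 ± 150 to 5.93 ± 4.16 (-4.86, SE 0.87, adjusted p = 0.00887), with 342, 287 and 58.6 FPKM in replicates 1, 2 and 3 of day 0. For every gene said here to rise or fall against day 0, all 3 libraries of the later day lay beyond the 3 of day 0.

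**Figure D2:**
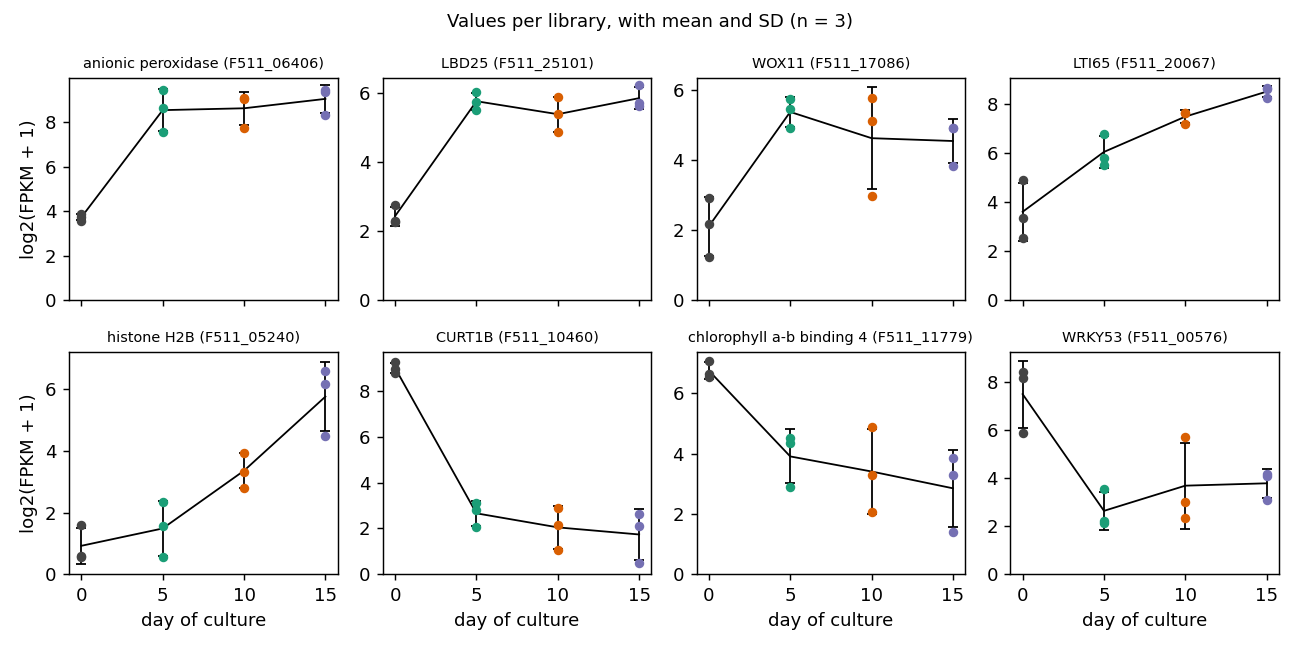
Expression of 8 named genes as log2(FPKM + 1) against the day in culture, 1 point per library, with the mean and SD of the 3 libraries of each day. CURT1B (CURVATURE THYLAKOID 1B) averaged 520 FPKM at day 0 and 2.97 at day 15, LBD25 rose from 4.51 to 54.3 FPKM by day 5, and histone H2B averaged 1.01 FPKM at day 0 and 63.5 at day 15.

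Photosynthesis lists were lower at day 5 with the preset correlation, but each of the 5 lists of photosynthesis, chloroplast ribosomes and senescence had an adjusted p = 0.968 with an estimated correlation. Of 34 photosystem and light-harvesting genes tested, 12 were called lower and 0 higher (25 and 0 adjusted over the list alone). Their median log2 fold change was -1.35 (quartiles -2.37 and -1.02, camera adjusted p = 1.09e-13). Of 17 Calvin cycle enzymes 5 were called lower and 0 higher (8 and 0 over the list alone; median -0.95, adjusted p = 0.00272). Among the 5, F511_04941 is a sugar phosphate transporter and not an enzyme of the cycle. Of 18 chlorophyll synthesis genes 6 were called lower and 1 higher (6 and 1 over the list alone; median -0.66, adjusted p = 6.99e-06). Of 38 chloroplast ribosomal protein genes 6 were called lower and 0 higher (10 and 0 over the list alone; median -0.67, adjusted p = 0.000118). In the list of chlorophyll breakdown and leaf senescence 3 of 17 genes were called lower and 1 higher (4 and 1 over the list alone; median -0.66, adjusted p = 0.0114). Pheophytinase (F511_08901), which removes phytol from pheophytin during chlorophyll breakdown, fell from 206 ± 20.1 to 61.8 ± 8.8 FPKM (-1.73, SE 0.25, adjusted p = 0.00416). Across days, replicate 3 was lower than the other replicates for photosystem genes (median -0.39), chloroplast ribosomal proteins (-0.39) and senescence genes (-0.37). Without day 5 replicate 3 the list calls for Calvin cycle, chloroplast ribosomal and senescence genes were lost (adjusted p = 0.0694, 0.0686 and 0.142). On replicates 1 and 2 only the senescence call was lost (0.14).

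Cytosolic ribosomal protein genes moved the other way. Of 141 tested, 137 had a positive log2 fold change, and 6 were called higher and 1 lower (7 and 1 adjusted over the list alone). The median was 0.66 (quartiles 0.55 and 0.78, camera adjusted p = 2.03e-25; adjusted p = 0.968 with an estimated correlation). The called exception, 40S ribosomal protein S5-2-like (F511_10475), fell from 169 ± 3.52 to 74.2 ± 13.3 FPKM (-1.20, SE 0.22, adjusted p = 0.00949). Replicate 3 was lower than the other replicates for this list by a median of -0.12.

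Auxin genes changed in both directions at day 5. Auxin response factor 5 (F511_30984), known as MONOPTEROS in Arabidopsis and needed there for embryonic root and vascular patterning, rose from 8.33 ± 4.41 to 31.9 ± 0.872 FPKM (1.93, SE 0.36, adjusted p = 0.0108). Auxin transporter-like protein 2 (F511_05500) rose from 29.1 ± 9.03 to 97.8 ± 26.6 (1.72, SE 0.25, adjusted p = 0.00416). Auxin-induced protein 22D-like (F511_09042), an Aux/IAA repressor, fell from 153 ± 100.7 to 3.02 ± 1.79 (-5.08, SE 0.78, adjusted p = 0.00509). GH3.1 (F511_31069), which conjugates auxin to amino acids, fell from 20.2 ± 13.1 to 1.10 ± 1.30 (-3.23, SE 0.60, adjusted p = 0.0103). Of 26 Aux/IAA and GH3 genes 5 were called lower and 2 higher (6 and 2 adjusted over the list alone; median -0.22, quartiles -0.97 and 0.13, camera adjusted p = 0.0126; adjusted p = 0.968 with an estimated correlation). Among the 2 higher genes is 60S ribosomal protein L14-2 (F511_02015), a part of the ribosome, whose call was lost without day 0 replicate 1 or day 5 replicate 1 or 3 (adjusted p up to 0.0593), after rescaling and on replicates 1 and 2 only. The list call was lost without day 0 replicate 3 (adjusted p = 0.0549). Of 22 auxin response factors 1 was called higher and 1 lower, 17 SAUR genes held 1 called higher, and of 23 auxin transport and synthesis genes 2 were called higher (the same counts adjusted over each list alone). None of these 3 lists passed (adjusted p = 0.553, 0.754 and 0.861). The medians of the SAUR and transport lists were 0.015 and 0.081 as deposited but -0.028 and -0.075 after rescaling, and camera's direction was down for both. Replicate 3 was higher than the other replicates for the auxin response factors, by a median of 0.35.

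Among regulators of organ formation, a few members rose and no list passed. LBD16-like (F511_01495), which acts in root and callus initiation in Arabidopsis, rose from 0.99 ± 0.269 to 7.95 ± 2.72 FPKM (2.13, SE 0.33, adjusted p = 0.00513). WUSCHEL-related homeobox 11-like (F511_17086), which acts in the first steps of root founder cells from leaf explants in Arabidopsis, rose from 3.81 ± 2.61 to 41.5 ± 11.6 (3.26, SE 0.66, adjusted p = 0.0134). This call was lost without day 0 replicate 1 or day 5 replicate 2 (adjusted p up to 0.0557). ERF114-like (F511_24774) had 0.60, 0.20 and 0 FPKM in the day 0 libraries and 10.9, 16.6 and 9.56 at day 5 (adjusted p = 0.00263). REVOLUTA-like (F511_40365), of a family that sets upper leaf identity, rose from 6.04 ± 1.20 to 14.8 ± 2.05 (1.17, SE 0.19, adjusted p = 0.00635). A gene described only as STM1 protein (F511_13273) had 0.07, 0.29 and 2.83 FPKM at day 0 and 32.53, 30.45 and 19.04 at day 5. That description does not state its family. The lists rest on text patterns, so they can miss members of a family. Of 22 LBD genes 3 were called higher and 0 lower (adjusted p = 0.305), and of 29 WOX, KNOX and BELL genes 2 and 0 (adjusted p = 0.752). Of 15 AP2 family regulators 1 and 0 (adjusted p = 0.846), and of 26 organ boundary and polarity genes 1 and 1 (adjusted p = 0.777). Adjusted over each list alone the 4 lists had 3, 2, 1 and 1 higher and 0 lower. The median of the boundary and polarity list was 0.0052 as deposited and -0.15 after rescaling, with camera's direction down.

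Cytokinin genes also went both ways at day 5. Adenylate isopentenyltransferase 3 (F511_03692), which makes cytokinin precursors, rose from 30.5 ± 15.8 to 154 ± 58.5 FPKM (2.32, SE 0.35, adjusted p = 0.0048). LOG3 (F511_39717), which releases active cytokinin, fell from 14.7 ± 4.52 to 2.46 ± 0.743 (-2.17, SE 0.35, adjusted p = 0.00595). Of 24 genes of type-A response regulators and cytokinin turnover 1 was called higher and 3 lower (2 and 3 adjusted over the list alone; median 0.52, camera adjusted p = 0.944).

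The jasmonate and ethylene lists were lower at day 5, with members called in both directions in the ethylene list. These and the early light-induced and cuticle lists had an adjusted p = 0.968 with an estimated correlation. Of 23 genes of jasmonate synthesis and JAZ repressors 3 were called lower and 0 higher (7 and 0 adjusted over the list alone; median -0.96, quartiles -1.66 and 0.18, camera adjusted p = 0.000911). Of 33 genes of ethylene synthesis and the ERF1 group 6 were called lower and 3 higher (9 and 3 over the list alone; median -0.45, adjusted p = 0.0124). Early light-induced proteins, 13 genes with 0 called, had a median of -0.86 (adjusted p = 0.0309). The 69 genes of cuticle and epidermis, with 1 called higher and 2 lower (1 and 1 over the list alone), had a median of -0.28 (adjusted p = 0.0466). ERF017-like (F511_34068) had 82.2, 79.3 and 11.1 FPKM at day 0 and 0, 0 and 0.82 at day 5 (adjusted p = 0.00705). WRKY40 (F511_32070) fell from 334, 241 and 27.0 FPKM to 5.10, 2.13 and 4.68 (-4.79, SE 0.90, adjusted p = 0.0107). In both genes, as in WRKY53, the last of the 3 day 0 values, from replicate 3, was the lowest. The ethylene list was lost without day 0 replicate 1 (adjusted p = 0.0517) or 2 (0.0515). The early light-induced list was lost without day 0 replicate 3 (0.147) or day 5 replicate 3 (0.261). The cuticle list was lost without day 0 replicate 3 (0.336), day 5 replicate 1 (0.149), day 10 replicate 1 (0.0652) or day 15 replicate 1 (0.0557). On replicates 1 and 2 only, the early light-induced (0.417) and cuticle (0.0568) calls were lost. Rescaling also ended the last 2 of these calls (adjusted p = 0.127 and 0.0943), and cuticle genes were higher in replicate 3 by a median of 0.41.

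In all, limma called 541 genes higher and 601 lower at day 5 (1142 of 17288 tested, 47.4% of them higher), and 11 of the 43 lists passed, 1 up and 10 down. The median log2 fold change of all genes was 0.14 before rescaling. Median-ratio rescaling lowered that median by 0.14 and gave 352 higher and 729 lower (32.6% higher). Of 102 calls of named genes at day 5, 53 were lost when 1 library was left out, with an adjusted p of at most 0.158. The number of genes called moved over 1.5 times without day 0 replicate 1 (445) or 2 (534) and without day 5 replicate 1 (451) or 2 (420). It was 2033 on replicates 1 and 2 only.

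The second comparison asked which genes differed from day 0 after 10 days. Low-temperature-induced 65 kDa protein-like (F511_20067), of a family induced by abscisic acid and cold, rose from 14.3 ± 12.6 FPKM at day 0 to 180 ± 31.1 at day 10 (3.87, SE 0.50, adjusted p = 0.00359). A translocator protein homolog (F511_18359), of a family of membrane proteins induced by abscisic acid, rose from 8.75 ± 8.66 to 119 ± 20.2 (3.97, SE 0.52, adjusted p = 0.00377). A chloroplast polyphenol oxidase I-like gene (F511_05840) fell from 349 ± 132 to 22.3 ± 16.1 (-4.09, SE 0.50, adjusted p = 0.00327). A NAC transcription factor (F511_12857) fell from 212 ± 89.2 to 15.0 ± 16.8 (-4.18, SE 0.64, adjusted p = 0.00699), and calmodulin-4 (F511_28583), a calcium sensor, from 143 ± 75.7 to 9.03 ± 8.14 (-4.11, SE 0.57, adjusted p = 0.00453). In a fit on only the 6 libraries compared, the polyphenol oxidase kept its call and the other 4 genes lost theirs (adjusted p = 0.05 for F511_20067 and F511_18359, and 0.0612 for F511_12857 and F511_28583).

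LEA proteins and dehydrins, which protect cells during drying, rose as a list at day 10 with the preset correlation. They, HSP70 genes and cytosolic ribosomal proteins had an adjusted p = 0.615 with an estimated correlation. Of 28 tested, 8 were called higher and 1 lower (10 and 2 adjusted over the list alone; median 1.36, quartiles 0.53 and 2.23, camera adjusted p = 0.0012). A dehydrin-like protein Dh2 gene (F511_17762) rose from 219 ± 30.8 to 1034 ± 229 FPKM (2.22, SE 0.25, adjusted p = 0.00248) and embryonic protein DC-8-like (F511_16650) from 22.2 ± 14.8 to 141 ± 12.9 (2.79, SE 0.45, adjusted p = 0.00768). The called lower member, a late embryogenesis (Lea)-like gene (F511_41947), had 106 ± 55.4 FPKM at day 0 and 23.2 ± 18.7 at day 10 (-2.23, SE 0.52, adjusted p = 0.0296). Its libraries overlapped between the 2 days, and the call was lost without replicate 1 or 2 of either day (adjusted p up to 0.117). Replicate 3 was lower than the other replicates for the LEA list by a median of -0.18. HSP70, HSP90 and heat shock factor genes had 6 of 59 called higher and 2 lower (8 and 2 over the list alone; median 0.41, adjusted p = 0.0344). This list call was lost without day 0 replicate 1 (0.0525) or day 10 replicate 2 (0.0868). Heat shock 70 kDa 4-like (F511_04348), a chaperone, rose from 136 ± 80.9 to 481 ± 27.5 (1.97, SE 0.32, adjusted p = 0.00813). Heat stress transcription factor A-4a (F511_01867) fell from 41.6 ± 6.87 to 16.4 ± 3.64 (-1.30, SE 0.22, adjusted p = 0.00999), a call lost without day 0 replicate 1 (0.051). On only the 6 libraries compared, the calls of F511_16650 (0.05), F511_41947 (0.125), F511_04348 (0.073) and F511_01867 (0.0612) were lost. Cytosolic ribosomal proteins were again higher, with 135 of 141 positive, 3 called higher and 1 lower (the same over the list alone; median 0.54, adjusted p = 3e-18).

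The photosynthesis lists stayed below day 0 at day 10 with the preset correlation, and they, the chloroplast ribosomal, senescence, jasmonate, ethylene, early light-induced and Aux/IAA lists had an adjusted p = 0.615 with an estimated correlation. Photosystem genes had a median of -1.06 with 2 of 34 called lower (2 over the list alone; adjusted p = 3.71e-10), and Calvin cycle enzymes -1.12 with 4 of 17 lower and 1 higher (9 and 1; adjusted p = 0.00128). The median was -0.71 for chlorophyll synthesis with 0 of 18 called (2 lower and 1 higher over the list alone; adjusted p = 2.49e-05) and -0.83 for chloroplast ribosomal proteins with 9 of 38 lower (14; adjusted p = 5.47e-08). It was -0.72 for chlorophyll breakdown and senescence with 3 of 17 lower and 0 higher (3 and 1; adjusted p = 0.00203). Chloroplast 50S ribosomal protein L24 (F511_21595) fell from 301 ± 25.6 to 128 ± 37.5 FPKM (-1.26, SE 0.20, adjusted p = 0.00756), a call lost on only the 6 libraries compared (0.0689). Jasmonate genes had 6 of 23 called lower (10 over the list alone; median -1.02, adjusted p = 1.09e-05), and ethylene and ERF1 genes 4 of 33 lower and 1 higher (8 and 2; median -0.44, adjusted p = 0.00291). Early light-induced proteins had 0 of 13 called with all 13 negative (0 over the list alone; median -0.97, adjusted p = 0.00586). Aux/IAA and GH3 genes had 5 of 26 lower (6; median -0.098, mean -0.51, adjusted p = 0.0276). Replicate 3 was lower than the others for the photosystem (-0.39), Calvin cycle (-0.64), chloroplast ribosomal (-0.39) and senescence (-0.37) lists. On replicates 1 and 2 only the day 10 medians were -0.58 for photosystem genes (adjusted p = 0.00187), -0.47 for senescence (0.0294) and -0.33 for early light-induced proteins, whose call was lost (0.18), with adjusted p = 0.705, 0.7 and 0.705 when the correlation was estimated. The Aux/IAA call was also lost on these replicates (0.0769). The Aux/IAA call was lost without day 0 replicate 3 (0.0916) or day 10 replicate 2 (0.0618), and the early light-induced call without day 0 replicate 3 (0.0581) or day 10 replicate 3 (0.0627).

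Several day 5 changes stood at day 10 with similar size. LBD25-like (F511_25101) had 43.0 ± 15.3 FPKM (2.96, SE 0.27, adjusted p = 0.0015), and LBD16-like (F511_01495) 7.61 ± 2.33 (2.08, SE 0.33, adjusted p = 0.00765). CURVATURE THYLAKOID 1B (F511_10460) had 3.70 ± 2.71 (-6.96, SE 0.56, adjusted p = 0.000835) and LOG3 (F511_39717) 1.65 ± 0.696 (-2.56, SE 0.35, adjusted p = 0.00424). ARR5-like (F511_13050), a type-A response regulator induced by cytokinin, rose from 8.63 ± 0.337 to 19.7 ± 4.73 (1.08, SE 0.18, adjusted p = 0.0091). Without day 10 replicate 1 its call was lost (adjusted p = 0.0405 with a fold below the minimum). WUSCHEL-related homeobox 11-like (F511_17086) had 31.4 ± 23.5 (2.51, SE 0.66, adjusted p = 0.043). This call was lost without any 1 of the day 0 libraries or day 10 replicate 2 or 3 (adjusted p up to 0.156). On only the 6 libraries compared, the calls of LBD16-like (0.0532), ARR5-like (0.0748) and WUSCHEL-related homeobox 11-like (0.137) were lost.

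At day 10 limma called 387 genes higher and 390 lower (777, 49.8% higher), and 12 of 43 lists passed (3 up and 9 down). Rescaling lowered the median of all genes by 0.15 and gave 247 higher and 503 lower (32.9% higher). Of 84 calls of named genes 51 were lost when 1 library was left out (adjusted p at most 0.169). The number called moved over 1.5 times without day 0 replicate 1 (200), 2 (289) or 3 (1175) or day 10 replicate 2 (300). A fit on only the 6 libraries compared gave 88 genes, and one on replicates 1 and 2 only gave 1492.

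The third comparison asked which genes differed from day 0 after 15 days. Histone H2B-like (F511_05240), a core histone, rose from 1.01 ± 0.898 FPKM at day 0 to 63.5 ± 38.2 at day 15 (4.84, SE 0.60, adjusted p = 0.0015). Late embryogenesis abundant protein 2-like (F511_06085) rose from 4.83 ± 2.57 to 291 ± 208 (5.54, SE 0.82, adjusted p = 0.00313) and low-temperature-induced 65 kDa protein-like (F511_20067) to 364 ± 53.3 (4.89, SE 0.50, adjusted p = 0.000756). Glutamate decarboxylase-like (F511_23720), which makes GABA, rose from 0.573 ± 0.169 to 44.3 ± 13 (4.82, SE 0.46, adjusted p = 0.000514). Chloroplast carbonic anhydrase (F511_22488), an abundant leaf enzyme, fell from 2272 ± 146 to 237 ± 273 (-3.92, SE 0.80, adjusted p = 0.0106).

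LEA proteins and dehydrins had the largest median of the 43 lists at day 15, and they, the abscisic acid list and the HSP70 list had an adjusted p = 0.506 with an estimated correlation. Of 28 tested, 16 were called higher and 1 lower (19 and 1 adjusted over the list alone; median 2.34, quartiles 1.05 and 3.22, camera adjusted p = 1.01e-06). The dehydrin Dh2 gene (F511_17762) reached 1458 ± 319 FPKM (2.72, SE 0.25, adjusted p = 0.000428), DC-8-like (F511_16650) 308 ± 57.9 (3.90, SE 0.45, adjusted p = 0.00108) and LEA D-34-like (F511_17223) 57.2 ± 21.1 from 2.36 ± 3.67 (4.62, SE 0.60, adjusted p = 0.00187). Across days the list was lower in replicate 3, by a median of -0.18. Abscisic acid signalling genes had 8 of 47 called higher and 0 lower (11 and 0 over the list alone; median 0.52, adjusted p = 0.00354). Of these, abscisic acid 8'-hydroxylase 4-like (F511_11778), which breaks the hormone down, rose from 0.273 ± 0.188 to 24.6 ± 16.4 (4.16, SE 0.53, adjusted p = 0.00168). HVA22-like protein a (F511_25902), of a family induced by abscisic acid, had 0, 0 and 1.21 FPKM at day 0 and 16.3, 29.6 and 16.8 at day 15 (adjusted p = 0.000428). HSP70, HSP90 and heat shock factor genes had 12 of 59 called higher and 2 lower (the same over the list alone; median 0.56, adjusted p = 0.00822). Heat stress transcription factor A-6b (F511_15266) rose from 5.48 ± 1.34 to 26.0 ± 8.20 (2.03, SE 0.28, adjusted p = 0.00232). Of 15 small heat shock proteins 5 were called higher (5 over the list alone; median 0.36, adjusted p = 0.228).

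The chloroplast and senescence lists were again lower at day 15, with an adjusted p = 0.506 in each when the correlation was estimated. Photosystem genes had 19 of 34 called lower (22 adjusted over the list alone; median -1.58, adjusted p = 1.08e-14), and chloroplast ribosomal proteins 24 of 38 (25; median -1.34, adjusted p = 1.96e-12). Calvin cycle enzymes had 10 of 17 lower and 1 higher (the same over the list alone; median -1.66, adjusted p = 3.38e-05), and chlorophyll synthesis 5 of 18 lower and 1 higher (9 and 1; median -0.99, adjusted p = 2.43e-07). Senescence genes had 4 of 17 lower and 1 higher (4 and 2; median -0.61, adjusted p = 0.00179). In the chlorophyll synthesis list 1 of the called lower genes, SCO1 homolog 1 (F511_29040), is known for copper delivery to mitochondrial cytochrome oxidase (-1.04, SE 0.14, adjusted p = 0.00186). Without day 15 replicate 3 it fell under the fold minimum (adjusted p = 0.012), as it did on replicates 1 and 2 only. Chlorophyll a-b binding protein 4 (F511_11779) fell from 109 ± 22.8 to 8.00 ± 6.02 FPKM (-3.91, SE 0.75, adjusted p = 0.00891). Rubisco activase (F511_06046), which keeps rubisco active, fell from 5109 ± 328 to 1259 ± 488 (-2.09, SE 0.36, adjusted p = 0.00627). A chloroplast transketolase-like gene (F511_28282) rose from 1.79 ± 0.708 to 16.2 ± 3.93 (2.63, SE 0.30, adjusted p = 0.00106). Replicate 3 was lower for the photosystem (-0.39), chloroplast ribosomal (-0.39), Calvin cycle (-0.64) and senescence (-0.37) lists.

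Jasmonate genes had 7 of 23 called lower at day 15 (11 adjusted over the list alone; median -1.23, adjusted p = 1.95e-05; adjusted p = 0.506 with an estimated correlation). Allene oxide synthase (F511_01073), an early enzyme of jasmonate synthesis, fell from 195 ± 66.9 to 45.2 ± 4.37 FPKM (-2.02, SE 0.29, adjusted p = 0.00268). Ethylene and ERF1 genes had 4 of 33 lower and 2 higher (6 and 5; median -0.35, adjusted p = 0.00944; adjusted p = 0.656 with an estimated correlation). The Aux/IAA and GH3 list had 4 of 26 lower (4; median -0.062, mean -0.50, adjusted p = 0.0161; adjusted p = 0.582 with an estimated correlation). Cytosolic ribosomal proteins had 134 of 141 positive, 2 called higher and 1 lower (3 and 1; median 0.45, adjusted p = 4.38e-09; adjusted p = 0.632 with an estimated correlation), with replicate 3 lower by a median of -0.12. The ethylene call was lost without day 0 replicate 1 (0.06) or 2 (0.0549), and the Aux/IAA call without day 0 replicate 3 (0.0578) and on replicates 1 and 2 only (0.167). LBD25-like (F511_25101) had 58.3 ± 13.9 FPKM (3.42, SE 0.27, adjusted p = 0.000403). The LBD list had 4 of 22 called higher and 1 lower (5 and 1 over the list alone; median 0.37, adjusted p = 0.167; adjusted p = 0.698 with an estimated correlation). After rescaling it passed upward with the preset correlation (median 0.25, adjusted p = 0.0323).

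Cell division and chromatin lists did not pass at day 15 over all libraries, but DNA replication did on replicates 1 and 2 only. Of 26 cyclins and cyclin-dependent kinases 0 were called (median -0.18, camera adjusted p = 0.214), and of 8 kinase inhibitors and cell-cycle brakes 0 (median 0.056 as deposited and -0.10 after rescaling, adjusted p = 0.401). DNA replication proteins had 2 of 43 called higher (median 0.34, adjusted p = 0.401). On replicates 1 and 2 only, a fit added after the data were seen, their median was 0.91 (adjusted p = 1.49e-05), 0.42 at day 5 (0.0414) and 0.44 at day 10 (0.0049), with adjusted p = 0.345, 0.826 and 0.7 when the correlation was estimated. The count was 3 of 51 higher for mitosis and cytokinesis proteins (median 0.0083 as deposited and -0.16 after rescaling, adjusted p = 0.762) and 1 of 13 for core histones (median 0.0038 as deposited and -0.21 after rescaling, adjusted p = 0.655). For the inhibitors, mitosis proteins and core histones camera's direction was down, and the inhibitors' mean was -0.18. The 65-kDa microtubule-associated protein 6-like gene (F511_23626), which bundles microtubules, rose from 10.3 ± 2.08 to 30.8 ± 6.65 FPKM (1.48, SE 0.28, adjusted p = 0.00851). Of 35 genes of DNA methylation 0 were called (median 0.12 as deposited and -0.094 after rescaling, adjusted p = 0.891), and of 12 DNA demethylases 0 (median 0.17, adjusted p = 0.712). Of 77 histone modifiers 1 was higher and 1 lower (median 0.28, adjusted p = 0.161). Adjusted over each list alone the counts were the same except for DNA replication (1 higher). Histone deacetylase HDT1-like (F511_32886) rose at day 5 from 21.9 ± 6.69 to 61.2 ± 2.88 (1.48, SE 0.23, adjusted p = 0.00509). Across days replicate 3 was higher for mitosis genes (median 0.40) and DNA methylation genes (0.33).

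At day 15 limma called 801 genes higher and 758 lower (1559, 51.4% higher), and 12 of 43 lists passed (4 up and 8 down). Rescaling lowered the median of all genes by 0.19 and gave 493 higher and 997 lower (33.1% higher). Of 117 calls of named genes 47 were lost when 1 library was left out (adjusted p at most 0.162). The number called moved over 1.5 times without day 0 replicate 1 (749) or 2 (986) or day 15 replicate 2 (923) or 3 (1021).

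**Figure D3:**
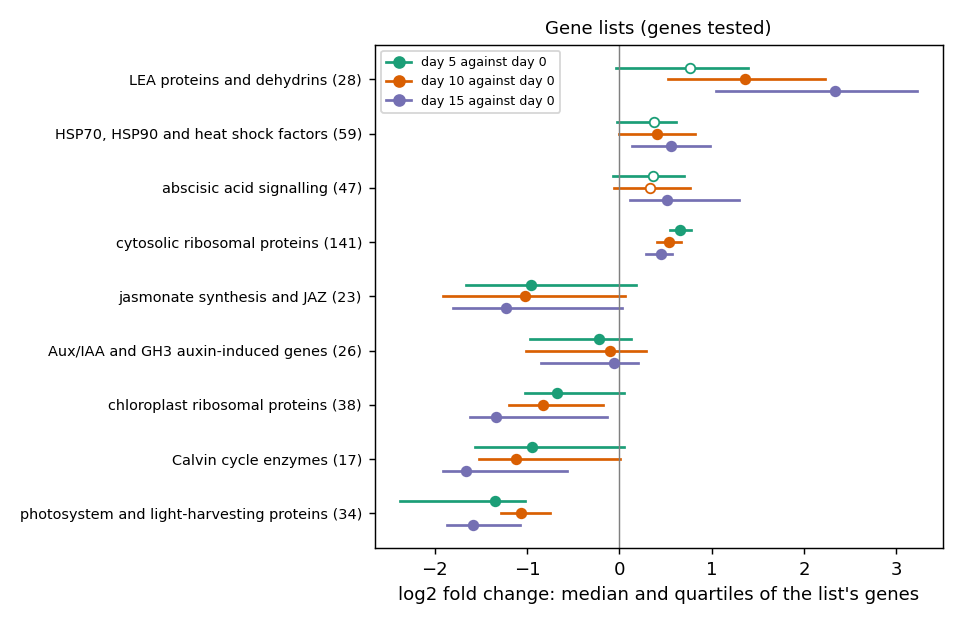
Median log2 fold change against day 0 of 9 gene lists at days 5, 10 and 15, with bars for the quartiles of the list's genes and filled points where camera with its preset correlation gave an adjusted p under 0.05. LEA proteins and dehydrins rose to a median of 2.34 at day 15 and photosystem genes stood at -1.58, and no filled point had an adjusted p under 0.05 with an estimated correlation (smallest 0.506 at day 15).

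Genes changed at all 3 days numbered 259 higher and 268 lower, with 0 genes called in opposite directions at different days. The peroxidase F511_06406, the vinorine synthase-like gene F511_24117 and gibberellin 3-beta-dioxygenase 1-like (F511_10046), which activates gibberellins, were among those higher, with log2 fold changes at day 15 of 5.32 (SE 0.49), 3.93 (SE 0.42) and 3.10 (SE 0.45). Pheophytinase (F511_08901) and polyphenol oxidase I-like (F511_05840) were among those lower (-2.0, SE 0.25, and -4.69, SE 0.50, at day 15). The 3 comparisons share the day 0 libraries, so part of this overlap may come from shared controls, and 3 control libraries are too few to split between comparisons. Independent lists of these sizes would share 0.561 and 0.594 genes, and 20 simulations without change but with shared controls called 0 genes at any day, so they cannot show how much overlap sharing gives. The fold changes at days 5 and 10, 5 and 15, and 10 and 15 correlated across genes, which are not independent replicates, with r = 0.883, 0.824 and 0.880, against 0.50, 0.50 and 0.50 in the simulations. The simulated libraries were independent, whereas real libraries of the same number correlated (up to 0.66 for days 5 and 10), which would raise the value without change. Their covariances were 0.511, 0.537 and 0.534 against 0.0883, 0.0884 and 0.0888. After rescaling 164 genes were higher and 347 lower at all 3 days (32.1% higher). The count of 527 moved over 1.5 times without day 0 replicate 1 (139), 2 (213) or 3 (826), day 5 replicate 1 (298) or 2 (284), or day 10 replicate 2 (220). It was 965 on replicates 1 and 2 only. At least 1 day had a call for 1007 genes higher and 1011 lower.

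Between days 5 and 10, LEA and dehydrin genes rose as a list (median 0.57, 24 of 28 positive, camera adjusted p = 6.47e-06) and so did auxin response factors (median 0.29, 18 of 22 positive, adjusted p = 0.00243) and photosystem genes (median 0.22, 30 of 34 positive, adjusted p = 0.0045). Cytosolic (median -0.13, 127 of 141 negative, adjusted p = 2.75e-08) and chloroplast ribosomal proteins (median -0.18, 34 of 38 negative, adjusted p = 0.0058) fell. Each of these 5 lists had an adjusted p = 0.993 with an estimated correlation and 0 members called, also over the list alone, and with replicate number as a block 6 lists passed. Across days replicate 3 differed from the other replicates in the same 5 lists, by medians of -0.18, 0.35, -0.39, -0.12 and -0.39 in the order given. limma called 0 genes between days 5 and 10, where 539 had an unadjusted p under 0.05, and the smallest adjusted p was 1. limma without trend and robust variances and limma with a replicate block also called 0. Without day 10 replicate 3 only 2 lists passed, and the chloroplast ribosomal list turned upward in that fit (adjusted p = 0.84). Without day 10 replicate 1 the photosystem list turned downward (0.178). The photosystem list was also lost without day 5 replicate 3 (0.48), and the chloroplast ribosomal list without day 5 replicate 1 (0.662) or 2 (0.343) or day 10 replicate 2 (0.0985). Auxin response factors were lost without day 5 replicate 1 (0.133) or day 10 replicate 3 (0.0936), the LEA list without day 5 replicate 3 (0.563) or on replicates 1 and 2 only (0.0605) and cytosolic ribosomal proteins without day 10 replicate 3 (0.072).

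Between days 10 and 15, early light-induced proteins, which bind chlorophyll and are induced by light stress and drying, rose as a list (median 1.92, 12 of 13 positive, camera adjusted p = 1.14e-08; 0 called, 4 higher adjusted over the list alone). So did LEA proteins and dehydrins (median 0.77, 26 of 28 positive, adjusted p = 6.03e-09; 0 called, 3 higher over the list alone) and abscisic acid signalling (median 0.26, adjusted p = 0.00572). These 3 lists had an adjusted p = 0.376 with an estimated correlation. Lists that also rose were HSP70, HSP90 and heat shock factors (median 0.18, adjusted p = 0.0351; adjusted p = 0.732 with an estimated correlation), lignin and secondary wall (0.23, 0.0302; adjusted p = 0.83 with an estimated correlation) and root endodermis and root hair (0.27, 0.0183; adjusted p = 0.703 with an estimated correlation). Photosystem genes (median -0.55, 32 of 34 negative, adjusted p = 3.41e-08; adjusted p = 0.732 with an estimated correlation) and chloroplast ribosomal proteins (-0.41, 33 of 38 negative, 3.04e-10; adjusted p = 0.703 with an estimated correlation) fell, as did chlorophyll synthesis (-0.30, 0.000522; adjusted p = 0.703 with an estimated correlation) and Calvin cycle enzymes (-0.40, 0.01; adjusted p = 0.732 with an estimated correlation). The others lower were cytosolic ribosomal proteins (-0.091, 1.32e-06; adjusted p = 0.754 with an estimated correlation), auxin response factors (-0.15, 0.022; adjusted p = 0.815 with an estimated correlation) and organ boundary and polarity regulators (-0.23, 0.012; adjusted p = 0.732 with an estimated correlation). Members called numbered 0 in every list here, and over the list alone also 0 except where given. On replicates 1 and 2 only, cyclins (median 0.54, adjusted p = 0.000966), DNA replication (0.41, 2e-05), mitosis (0.42, 5.27e-05) and core histones (0.54, 2.33e-05) also passed upward, with adjusted p = 0.353, 0.339, 0.353 and 0.353 when the correlation was estimated, against medians of 0.15, 0.047, 0.18 and 0.18 over all libraries.

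In this comparison limma called 0 genes, with 561 at an unadjusted p under 0.05 and a smallest adjusted p of 0.188. limma without trend and robust variances called 1 and limma with a replicate block 0, and 14 lists passed with the block against 13 without. On replicates 1 and 2 only, a fit added after the data were seen, 22 genes were called. Only 6 lists passed without day 10 replicate 1 and 8 without day 15 replicate 2. Without day 10 replicate 1 the calls lost were photosystem (0.794), Calvin cycle (0.794), chlorophyll synthesis (0.661), cytosolic ribosomal (0.157), boundary and polarity (0.279), HSP70 (0.121), lignin (0.714) and root genes (0.0643). Without day 10 replicate 2 the root list was lost (0.0667), and without day 10 replicate 3 auxin response factors (0.372), boundary and polarity (0.118) and HSP70 (0.213). Without day 15 replicate 1 auxin response factors (0.0963), HSP70 (0.105) and lignin (0.0557) were lost, and without day 15 replicate 2 auxin response factors (0.171), HSP70 (0.135), abscisic acid (0.0913), lignin (0.353) and root genes (0.067). Without day 15 replicate 3 photosystem (0.166), Calvin cycle (0.384), chlorophyll synthesis (0.0673), cytosolic ribosomal (0.547), boundary and polarity (0.247) and root genes (0.102) were lost. The calls for LEA, early light-induced and chloroplast ribosomal genes held without each single library. On replicates 1 and 2 only, auxin response factors (0.133) and boundary and polarity genes (0.42) were lost.

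Over the 4 days together, the F test found 1525 genes changed at an adjusted p under 0.05, and 1145 after rescaling. With replicate number as a block it was 2770, where libraries of the same number correlated between later days, and on replicates 1 and 2 only it was 2377. The count moved over 1.5 times without day 0 replicate 1 (199) or 2 (272), day 5 replicate 1 (739) or 2 (708), day 10 replicate 2 (934) or day 15 replicate 2 (715).

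In leaf DNA, the question was where methylation differed between young and mature leaves. In the CG context the authors' deposited table listed 2247 regions, 1193 higher in mature and 1054 higher in young leaves (53.1% higher in mature), with a median length of 176 bp and 6 CG sites. A region downstream of the RNA helicase gene DHX35 (F511_03011, scaffold KQ987269.1, 91441 to 92356) had the largest positive difference of the named regions, with a level of 0.865 in mature and 0.107 in young leaves. The largest negative difference of the named regions was upstream of a somatic embryogenesis receptor kinase 1-like gene (F511_00902, scaffold KV009364.1, 867989 to 868129), a receptor kinase family named for its role in embryo formation from cultured cells, with 0 in mature and 0.835 in young leaves. The same region lay upstream of a calcium uptake protein 1-like gene (F511_00903). An exon of argonaute 1 (F511_00679, scaffold KV005017.1, 583172 to 583272), which acts in small RNA silencing, had 0 in mature and 0.804 in young leaves. Levels rest on 1 library per leaf age with unknown coverage, and the p-values are the authors' own, with no adjustment stated, the largest being 0.0498.

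Regions higher in mature leaves had a median level of 0.97 there and 0.808 in young leaves, and regions higher in young leaves 0.901 there and 0.58 in mature leaves, per the authors' deposited table. Of the CG regions 42.9% were tied to no gene, and of those 59.7% were higher in mature and 389 regions higher in young leaves. Upstream of genes 126 of 280 regions (45%) were higher in mature leaves and downstream 163 of 369 (44.2%). Among members of the gene lists, the auxin-responsive IAA29-like gene (F511_02556) had a downstream region at 0.72 in mature and 0 in young leaves. Its expression fell at day 5 (-2.20, SE 0.55, adjusted p = 0.0277) and day 10 (-2.34, SE 0.55, adjusted p = 0.0291) but was not called at day 15 (-1.50, adjusted p = 0.0811), and these calls were not refitted without single libraries. Cyclin-D4-1-like (F511_00037), which acts at entry into the cell cycle, had an exon region at 0 in mature and 0.61 in young leaves, and AIL6 (F511_00049), of the AINTEGUMENTA family, a coding region at 0.30 and 0.926. Histone deacetylase 5 (F511_00595) had a coding region at 0.40 and 0.932, and condensin complex subunit 2 (F511_01536) 3 regions, each lower in mature leaves. Expression of these 4 genes was not called at any day (adjusted p at day 5 of 0.288, 0.612, 0.708 and 0.263). A region upstream of 4-coumarate--CoA ligase 1-like (F511_02506), an early enzyme of lignin synthesis, had 0.123 in mature and 0.667 in young leaves. Its expression fell at day 15 (-1.48, SE 0.29, adjusted p = 0.00948).

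The CHG table listed 1548 regions, 976 Up and 572 Down for BhB over BhS (63% Up). For CHH it was 1738 regions on the positive strand (1455 Up and 283 Down) and 1610 on the negative strand (1347 Up and 263 Down), 83.7% Up in both. Of these regions 65.2%, 67% and 65.2% were tied to no gene. The labels do not say which leaf age BhB and BhS are, so no leaf age is given for these directions and no levels were used. All 4 tables covered the same 18 scaffolds of 5817 in the expression table, and what selected these scaffolds is not stated.

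**Figure D4:**
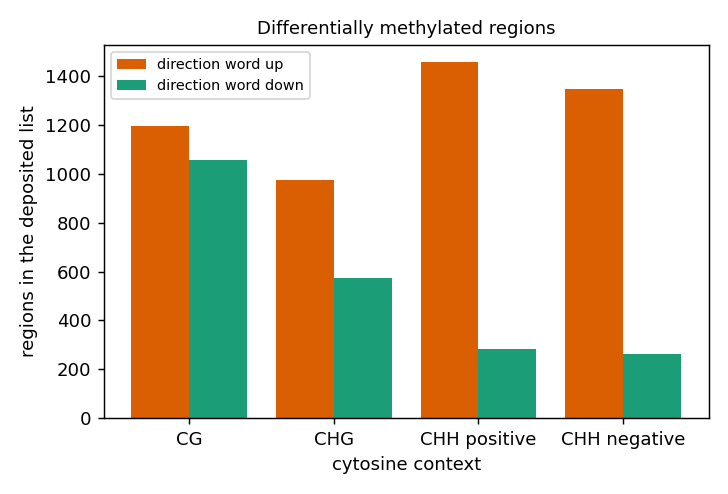
Number of listed regions per context, as bars for regions Up and Down in the authors' deposited tables. For CG regions Up is mature over young leaves (1193 and 1054), and for CHG (976 and 572), CHH positive (1455 and 283) and CHH negative strands (1347 and 263) it is BhB over BhS, names that the labels do not define.

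CG and CHG regions overlapped in 193 pairs, of which 91.2% carried the same word. CHH regions of the positive and negative strands overlapped in 237 pairs (86.1% with the same word). CG regions overlapped those of the CHH positive strand in 93 pairs (62.4%) and of the negative strand in 82 (62.2%), and CHG regions in 70 (70%) and 95 (76.8%). The word in the CG table compares mature with young leaves and in the other tables BhB with BhS, so a shared word across these tables is not shown to be a shared direction.

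Genes with a region were compared with other tested genes for calls in culture. Of 674 tested genes with a CG region 63 were called in any comparison with day 0 (9.35%), against 1955 of 16614 others (11.8%; odds ratio 0.773, Fisher's exact p = 0.0576, adjusted p = 0.522). For a region in any context it was 88 of 830 (10.6%) against 11.7% (odds ratio 0.893, adjusted p = 0.844). The odds ratios for CHG, CHH positive and CHH negative regions were 0.779, 1.19 and 1.02 (adjusted p = 0.862, 0.844 and 0.94). Of the 30 exact tests 0 passed, and 2 had an unadjusted p under 0.05. In 48 called genes all CG regions went 1 way. Of these 9 were higher and 5 lower in culture with regions higher in mature, and 13 and 21 with those higher in young leaves (odds ratio 2.91, exact p = 0.122, adjusted p = 0.488). The same ratio was 0.875, 0.765 and 1 for the words of the CHG, CHH positive and CHH negative tables (exact p = 1 in each). Only 1148 tested genes lay on the 18 scaffolds, and against the other genes there the odds ratio for CG regions was 0.585 (exact p = 0.0038, adjusted p = 0.114).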

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

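Of the tests weighed here, those on relative depth, on added reads, on genotype and on replicates 1 and 2 were chosen only after the result was seen. The values below passed a test of the difference between the effects of successive times, with the preset correlation, and each was lost with an estimated correlation.

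Between days 5 and 10, LEA proteins and dehydrins differed by a median log2 fold change of 0.568 and auxin response factors by 0.287. Photosystem and light-harvesting proteins differed by 0.219, cytosolic ribosomal proteins by -0.13 and chloroplast ribosomal proteins by -0.182. The adjusted p = 0.993 with an estimated correlation for each of these 5 lists.

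Between days 10 and 15, early light-induced proteins differed by a median of 1.92, LEA proteins and dehydrins by 0.768, and abscisic acid signalling genes by 0.255 (adjusted p = 0.376 with an estimated correlation in each). Root endodermis and root hair markers differed by 0.266, chlorophyll synthesis enzymes by -0.298 and chloroplast ribosomal proteins by -0.41 (adjusted p = 0.703 with an estimated correlation in each). HSP70, HSP90 and heat shock factors differed by 0.179, photosystem proteins by -0.554, Calvin cycle enzymes by -0.396 and boundary and polarity regulators by -0.234 (adjusted p = 0.732 with an estimated correlation in each). Cytosolic ribosomal proteins differed by -0.0913 (adjusted p = 0.754 with an estimated correlation), auxin response factors by -0.15 (0.815) and lignin and secondary wall genes by 0.234 (0.83).

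The rise of LEA proteins and dehydrins to day 15 was weighed against 3 explanations. The replicate 3 libraries alone were argued against, since replicates 1 and 2 gave a median of 2.88 at day 15. A water-deficit response might raise galactinol and raffinose enzymes and NCED, but their median was -0.252 over 8 genes, 2 of them also in fixed lists. The bound written before this result was a median of 0 or lower, which excludes the explanation; after the value was seen the bound was tightened to an upper quartile of 0 or lower, as the 8 genes went both ways, and by the tightened bound it stays open. A seed maturation programme stays open too, with a median of 0.171 over 20 seed storage and oil body proteins, 10 of them also in fixed lists, and so does the day in culture itself, untested as a cause.

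The replicate 3 libraries stood apart at every day, and no biological explanation in the design was tested for it. A difference in depth stays open. The relative depth of replicate 3 differed from the mean of replicates 1 and 2 by at most 1.11-fold within a day, but only 1 of 8 simulated libraries with a depth 2 times as high came out at 1.5 or more, so this test is void, and replicate 3 had the fewest genes at 0 FPKM at each day. Plants of another genotype in replicate 3 are a candidate explanation: 20 genes were on in all 4 replicate 3 libraries and off in all others or the reverse (13 and 7), against 0 for replicate 1 and 1 for replicate 2. Of these 20 genes 14 had no locus tag, as had 1798 of all 24110 genes. Added reads from another organism or cell type could give the 13 genes but not the 7 lost ones, and as 7 is under the bound of 10 set for that test, this stays open for the rest of the difference.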

How the results depend on the processing

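The fits on replicates 1 and 2 only, the same-scaffold background and the sign at day 15 were alternatives chosen after seeing the data. Of 303 calls of named genes 0 reversed under any setting, while 151 were lost without at least 1 library (508 of 1818 fits), 99 on the 6 libraries compared, 35 without the filter, 27 after rescaling, 24 on replicates 1 and 2, 14 with a pseudocount of 0.1, 14 without trend and robust variances and 4 with the replicate block.

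Counts of changed genes depended on single libraries and on the choice of fit. Leaving out 1 library gave 420 to 1412 genes at day 5, 200 to 1175 at day 10, 749 to 1886 at day 15, 199 to 1747 over the time course and 139 to 826 at all 3 times. The cause was not tested. Without a fold minimum the counts at days 5, 10 and 15 were 2149, 1397 and 2909, by construction, and 65.2%, 62.6% and 64.9% of them were higher, against 47.4%, 49.8% and 51.4% with it and 32.6%, 32.9% and 33.1% after rescaling. The 6 libraries of days 0 and 10 alone gave 88, and the replicate block gave 2770 over the time course. Replicates 1 and 2 only gave 2033 at day 5, 1492 at day 10, 1 between days 5 and 10, 22 between days 10 and 15, 2377 over the time course and 965 at all 3 times. Between days 10 and 15 no filter gave 1 gene and limma without trend and robust variances 1 gene. The cause of these changes was not tested. Rescaling gave 1081, 750 and 1490 genes against day 0, within 1.5 times of the counts as deposited.

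With an estimated correlation 0 lists passed at day 5, 0 at day 10, 0 at day 15, 0 between days 5 and 10 and 0 between days 10 and 15. Of 636 refits of the 53 list calls without 1 library, 579 passed in the same direction, 55 did not pass and 2 turned direction. These were the list photosystem and light-harvesting proteins, day 10 vs day 5 (adjusted p = 5.34e-10 without YL-10d replicate 3, 0.178 and turned without day 10 replicate 1, 0.48 without day 5 replicate 3) and the list chloroplast ribosomal proteins, day 10 vs day 5 (5.12e-13 without YL-10d replicate 1, 0.84 and turned without day 10 replicate 3, 0.662 and 0.343 without day 5 replicates 1 and 2, 0.0985 without day 10 replicate 2). The cause was not tested. Without 1 library 2 to 7 lists passed between days 5 and 10 and 6 to 15 between days 10 and 15. All 53 calls passed with the replicate block, 51 after rescaling and 44 on replicates 1 and 2. The 9 lost there were senescence (0.14), early light-induced (0.417) and cuticle (0.0568) at day 5, Aux/IAA (0.0769) and early light-induced (0.18) at day 10, Aux/IAA at day 15 (0.167), LEA between days 5 and 10 (0.0605), and auxin response factors (0.133) and boundary genes (0.42) between days 10 and 15. Lists that passed on replicates 1 and 2 but not over all libraries, besides the cell division lists in the text, were LEA proteins (median 1.55, adjusted p = 0.00101) and HSP70 (0.38, 0.0414) at day 5, DNA demethylases (0.34, 0.031) and cuticle (0.28, 0.0168) between days 5 and 10, and flavonoid (0.31, 0.0379), cuticle (0.38, 0.0379) and reference genes (0.22, 0.0202) between days 10 and 15, all upward. With an estimated correlation on these replicates none passed in any comparison (smallest adjusted p = 0.339), and the cause of the change was not tested. Medians that moved over 1.5 times or turned on these replicates, besides those in the text, were ethylene at days 5 and 15 (-0.77 and -0.64), Aux/IAA at day 15 (0.095), cuticle at day 5 (-0.16), photosystem between days 5 and 10 (0.45), and between days 10 and 15 cytosolic ribosomal (-0.022), auxin response factors (-0.097), boundary (-0.096) and lignin (0.39). Rescaling gained LBD genes at day 15, abscisic acid at day 10 (0.0377, from 0.0644), and small heat shock (0.0428, from 0.0547) and flavonoid genes (0.0428, from 0.104) between days 10 and 15. The cause of these moves and gains was not tested.

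An authors' p under 0.005 left 550 CG and 279 CHG regions, and 1124 CG regions had at least the median difference, by construction. Named 5-site regions had this p at 0.00794 or more, even at 0 against 0.804, so the cut also depends on site number. Odds ratios for genes with a region lay on both sides of 1, and 0 of 30 tests passed in any setting. On the other side lay 12 without a fold minimum, 9 without the filter, 3 in the logistic model and 3 on the same scaffolds. For any call these were CG 1.13, CHG 1.3 and any context 1.14 without a fold minimum, CG 1.07 and any context 1.16 without the filter, and CHH negative 0.987 in the logistic model. For direction they were CHG 1.05, CHH positive 1.76 and CHH negative 1.49 without a fold minimum, and CHH positive 1.22 and CHH negative 1.34 with the sign at day 15. The cause was not tested, and no direction is read here. Odds ratios reported were limited to those in the text after turns were seen. The median cut was not run for CHG and CHH, whose levels were not used.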

Other observations

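Cell wall, sugar and pigment genes held strong single changes without a list of theirs passing against day 0. A polygalacturonase-1 non-catalytic subunit beta-like gene (F511_18275), of a family of cell wall proteins tied to pectin breakdown, rose from 128 ± 24.5 FPKM to 2466 ± 581 at day 5 (4.24, SE 0.37, adjusted p = 0.000817). Sucrose synthase 2 (F511_16986), which cleaves sucrose, rose from 9.78 ± 7.76 to 109 ± 21.8 at day 15 (3.56, SE 0.39, adjusted p = 0.00106), and the sucrose transporter SUC4-like (F511_16025) from 46.1 ± 17.4 to 231 ± 8.85 (2.36, SE 0.27, adjusted p = 0.00106). Flavonol synthase-like genes went both ways: F511_15015 rose from 28.1 ± 7.81 to 86.8 ± 13.7 at day 15 (1.61, SE 0.21, adjusted p = 0.00191), and F511_29741 fell from 50.1 ± 22.7 to 1.28 ± 1.33 at day 5 (-4.53, SE 0.68, adjusted p = 0.00475). In each, 3 of 3 later libraries lay beyond day 0.

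At day 15 pectin modification had 10 of 77 genes higher and 4 lower (10 and 4 adjusted over the list alone; median 0.35, adjusted p = 0.837) and lignin and secondary wall 7 of 90 higher and 3 lower (5 and 3; 0.20, 0.939). Sucrose and sugar transport had 3 of 29 higher and 2 lower (4 and 3; median 0.25, adjusted p = 0.762). Flavonoid genes had 7 of 70 higher and 3 lower (8 and 3; median 0.10, after rescaling -0.057, adjusted p = 0.701). Expansins and xyloglucan genes had 2 of 33 higher and 5 lower (3 and 6; median 0.18, after rescaling -0.012, mean -0.019, adjusted p = 0.401). Defence proteins had 6 of 82 higher and 4 lower (6 and 4; median 0.14, after rescaling -0.031, adjusted p = 0.655). For the last 3 lists camera's direction was down although the median was positive. Among called members that do not do what a list's name says were extensin-like wall proteins (F511_24984 and F511_08622) under defence. NPR5-like (F511_19553), of a family that patterns leaves, was also under defence. Tetraketide alpha-pyrone reductase 1-like (F511_27485), of pollen wall synthesis, was under lignin. A gene described as protochlorophyllide-dependent translocon component 52 (F511_33973) was under chlorophyll synthesis.

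Among markers of cell types, CASP-like protein PIMP1 (F511_11277) rose from 13.3 ± 6.69 to 147 ± 42.2 FPKM at day 5 (3.43, SE 0.47, adjusted p = 0.00363), and root endodermis and root hair markers had 1 of 32 called higher and 1 lower (1 and 1 adjusted over the list alone; median 0.32, adjusted p = 0.761). Guard cell markers had 4 of 26 higher at day 5 (4 higher and 1 lower; 0.23, 0.761), among them nepenthesin-1 (F511_03395), an aspartic protease. Xylem markers had 0 of 7 called (0; median 0.024 but camera's direction down, after rescaling -0.12 and up, adjusted p = 0.944), phloem markers 0 of 12 (0; -0.18, 0.477) and flower and seed markers 1 of 41 higher (1; 0.16, 0.815). The reference list had 4 of 63 higher and 0 lower at day 15 (4 and 0; median 0.40, adjusted p = 0.052). In it elongation factor 1-alpha-like (F511_06854) had 534 ± 25.0 FPKM at day 0 and 1152 ± 97.7 at day 15 (1.11, SE 0.19, adjusted p = 0.00555), a call that rescaling brought under the fold minimum (0.89).

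The tests on the following pattern were all chosen only after it was seen. The transcription factor genes WRKY53, WRKY40 and ERF017-like fell from day 0 to day 5, and no fixed list of such factors was tested. In replicate 3 WRKY40 had 34.4 FPKM at day 10 against 27.0 at day 0, and its calls at days 10 and 15 were lost without 4 and 5 of the single libraries. Library scaling stays open, as rescaling could only lower the ethylene and ERF1 median at day 5 (-0.564). An early wound and touch response present at day 0, for example from the preparation of the leaf pieces, is a candidate explanation. In a list of 33 other early wound and touch genes, 11 of them also in fixed lists, 6 were called lower at day 5, with a median of -1.16 (camera p = 3.68e-05, and p = 0.262 with an estimated correlation). The labels do not say how long the day 0 pieces waited, and the day of culture itself stays open as an untested explanation.

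Other splits of the libraries were counted for each comparison. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. The genes called numbered 1142 at day 5 with a highest other of 0, 777 at day 10 with 0, and 1559 at day 15 with 1, so 1 of 10 splits gave as many in each. The number was 0 with 0 between days 5 and 10 and 0 with 1 between days 10 and 15. In both 10 of 10 splits gave as many. For lists passing with the preset correlation the real value and the highest other were 11 and 15 at day 5 (4 of 10 splits gave as many), 12 and 11 at day 10 (1), 12 and 13 at day 15 (5), 5 and 12 between days 5 and 10 (9), and 13 and 12 between days 10 and 15 (1). Of 100 drawn splits of the 12 libraries only the real one gave 1525 genes over the time course and 527 at all 3 times. Others gave at most 746 and 1. As 1 of 100 is the lowest possible share and same-number libraries correlated, chance is not excluded.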
